A study of Mus musculus with 8 samples.

How the data were processed

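RNA was measured in 8 mouse ES cell cultures at day 0 or day 6 of differentiation. They carried 2 normal copies of Nkx2-5 or 1 copy with R141C, with 2 cultures in each of the 4 groups. Per the labels, differentiation went through embryoid bodies, with 2 days in hanging drops of 800 cells, 3 days in suspension and plating at day 5 for 24 hours. Cy3-labelled cRNA was made from 300 ng of RNA and hybridized to 1 single-colour Agilent array per culture. All arrays were on 1 slide and came from 1 scan. Day 0 arrays filled 1 column of the slide and day 6 arrays the other, with wild type above R141C, so position on the slide could not be separated from the groups.

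Per the file headers, the scanner files were made with Agilent Feature Extraction 11.5.1.1, while the labels give 10.5.1.1. Their processed signal is an intensity on a linear scale, deposited with background subtracted and trends removed within the array, and not normalized between arrays. The mean spot signal and the median local background are also deposited as intensity values, without correction. The deposited spot flags (other) are 0 or 1 per spot. The deposited series matrix holds log2 values of 36388 probes. Its columns had nearly equal quantiles, with medians of 8.99 to 9.04, as quantile normalization would give, and the filter that emptied its other probes is not stated. Its values correlated across probes with log2 of the processed signal of the same array, with r of 0.9995 to 0.9999.

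Each array had 62976 spots, of which 59305 were not controls. Spots marked as outliers (131 to 251 per array) were left out, as were 98 probes with no spot left on some array. No spot was saturated. Spots of 1 probe were averaged, and log2 of the processed signal was shifted so that the 75th percentile of each array was 0. Log2 signals below are on this scale. Probes were named by accession, symbol or synonym from a table of current mouse gene names, which renamed 2032 of 55681 probes and gave 34779 names, of which 22372 were current symbols. Positions are those of the probes on mm9 in the files. Each gene was represented by its probe with the highest mean signal over the 8 arrays. A gene was tested if that probe was well above background on both arrays of at least 1 group, which kept 25892 of 34736 names with a value (74.5%). The number of arrays limits the precision. The probe for Nkx2-5 measures the transcript and does not show the point mutation, so genotypes are those of the labels.

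Genes were tested with limma 3.58.1 in R 4.3.3 (data.table of version 1.17.8, statmod 1.5.0), with 1 model of 4 group means on all 8 arrays, 4 residual and 2.70 prior degrees of freedom, and Benjamini-Hochberg adjustment over the 25892 genes in each comparison. Tests were two-sided, and an adjusted p under 0.05 was called a change, with no minimum fold. The 5 comparisons were R141C against wild type at day 6 and at day 0, day 6 against day 0 in each genotype, and the difference of the genotype effect between the days. A fixed collection of 35 gene lists (764 entries, 702 genes) was tested with camera at its preset correlation between genes of 0.01, for lists with at least 5 tested genes, adjusted over lists in each comparison. Camera with an estimated correlation and fry were alternatives. A fold against a group in which no probe of the gene was well above background on any array is a lower bound, taken against the lowest normalized signal among bright probes, and is given as at least N-fold. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

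The groups, comparisons, tests, lists, alternatives and the rule for naming genes were fixed before the data were examined. The rule named Nkx2-5 in every comparison. Among genes past the threshold with a gene symbol and without overlap between groups, it named the 10 largest rises and falls for R141C against wild type at each day and for day 6 against day 0 in wild type, and the 5 largest each way in the other comparisons. Where a lower bound applied, it gave the size. Where no gene passed, it named the 5 with the smallest p in each direction as values. From each list described it named up to 4 passing genes with the largest change or, where none passed, up to 2 with the highest mean signal. Genes outside this rule are said to have been chosen after their values were seen. Results of 2 genes that the rule named are not reported here.

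The alternatives were quantile normalization, a median shift, normexp background correction with an offset of 50, the deposited series matrix values, no filter on dim probes, a filter on all 8 arrays, eBayes with trend and robust settings, only the arrays compared, a minimum fold of 2, the mean of a gene's probes, a replicate block, and leaving out each array in turn. Chosen after the data had been seen were leaving out 2 R141C arrays together, removing the median of each chromosome, crossed replicate pairs at day 0 and a replicate block within each genotype. Tested on simulated data for R141C against wild type at day 6, the model called none of 200 seeded genes at a log2 change of 1, 57% at 2 and 88.5% at 4, with 0, 5 and 11 other genes called. The simulated noise was normal, independent between genes and of 1 spread per gene in all groups. In the data, the median absolute log2 difference between replicates at day 6 was 0.365 in R141C and 0.171 in wild type. The rates may therefore not hold for the data.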

Results

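The series measured gene expression in wild-type mouse embryonic stem cells and in cells heterozygous for R141C, a missense change in the homeobox factor Nkx2-5. Cultures were taken before differentiation (day 0) and after 6 days of differentiation toward the heart lineage in embryoid bodies. Each of the 4 groups had 2 biological replicates. The number of probes well above background ranged from 31041 to 39258 per array (55.7% to 70.5%), and the 75th percentile of the processed signal from 936 to 1848. Correlations between replicate arrays, across genes, were 0.983 in wild type and 0.986 in R141C at day 0, and 0.994 and 0.982 at day 6. At day 0, wild-type replicate 1 was closer to both R141C arrays (0.991 and 0.987) than to its own replicate, and R141C replicate 1 was closer to it than to its own replicate. Wild-type replicate 2 had the 3 lowest correlations among the day 0 arrays (0.9825, 0.9847 and 0.9765). At day 6, R141C replicate 2 was closer to the 2 wild-type arrays (0.988 and 0.989) than to its own replicate. The replicates differed by more than 2 on the log2 scale for 569 genes in wild type and 322 in R141C at day 0, and for 105 and 521 genes at day 6.

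At day 6, the comparison of R141C with wild type asked how the cells differed on the way to the heart. Each genotype had its own slide positions and no second line is in the labels, so differences cannot be assigned to the mutation. Few single genes passed, and none of them belonged to the heart lists fixed beforehand. The genes of the contractile apparatus were nearly all lower in R141C, by amounts that differed between its 2 cultures, 19 of 27 cardiac transcription factors were lower, and genes of the interferon response and most Hox genes were higher. None of these lists was called with an estimated correlation (smallest adjusted p = 0.155). Nkx2-5 itself differed little.

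In limma, 17 of 25892 genes changed, 7 higher and 10 lower in R141C. At an unadjusted p under 0.05 there were 2209 genes, 1333 higher and 876 lower. The groups did not overlap for 44.3% of genes, where chance gives 33.3%. Srgn was above background on all 8 arrays (probe A_55_P2094925, chromosome 10, 61957432 to 61957491). Its log2 signal went from -3.81 ± 0.07 in wild type to -0.65 ± 0.41 in R141C (SD, n = 2), 8.99-fold (adjusted p = 0.0348). Clec4a3 (A_51_P147274, chromosome 6, 122919637 to 122919696), Ces2h (A_55_P2139431, chromosome 8, 107544251 to 107544310), Hoxaas3 (A_55_P2304482, chromosome 6, 52160572 to 52160631) and Gria1 (A_55_P2113758, chromosome 11, 57143613 to 57143672) were above background on both R141C arrays at day 6 and on no other array. They were at least 4.70-fold, 3.78-fold, 3.27-fold and 2.89-fold higher, with adjusted p of 0.0429, 0.0250, 0.0286 and 0.0327. Shisa3 (A_55_P2181104, chromosome 5, 68003415 to 68003474) went from -0.77 ± 0.24 to -4.88 ± 0.80 (SD, n = 2), 17.2-fold lower with an adjusted p of 0.0391. It was above background on 1 of the 2 R141C arrays at day 6, so its fold is imprecise. Smpd3 (A_52_P537545, chromosome 8, 108776790 to 108776849) was 7.73-fold lower, Foxd1 (A_52_P128134, chromosome 13, 99126452 to 99126511) 6.80-fold and Sncaip (A_52_P59264, chromosome 18, 53075430 to 53075489) 4.78-fold, with adjusted p of 0.0293, 0.0286 and 0.0293. Lrrc39 (A_52_P419373, chromosome 3, 116285807 to 116285866) was above background on both wild-type arrays at day 6 and on no other array, and was at least 2.33-fold lower in R141C (adjusted p = 0.0250). The other 7 were intervals, predicted genes or unnamed transcripts, 2 higher and 5 lower. Chosen among them after its values were seen, probe A_30_P01032687 (chromosome 5, 120280943 to 120281002), in an interval upstream of Tbx5, was 14.6-fold lower in R141C (adjusted p = 0.0293), with the same limit as Shisa3. Another tested probe in that interval, starting at 120279227, differed by -0.32 in limma (adjusted p = 0.762). The count differed with the array left out. No gene was called without 1 of R141C day 0 replicate 1 or 2, wild-type day 6 replicate 1 or 2, or R141C day 6 replicate 1, and 8 were called without either wild-type day 0 array (7 of the 17). Without R141C day 6 replicate 2, 117 genes were called, 14 of the 17 among them. The folds and bounds of the 10 named genes moved by less than 1.5 times whichever array was left out. With only the arrays compared, with either other filter on dim probes, or with the trend and robust settings, 0 genes passed, 5 with normexp and 1 with the deposited values.

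Nkx2-5 (A_51_P173285, chromosome 17, 26975621 to 26975680) had a log2 signal of 1.86 ± 0.10 in wild type and 1.56 ± 0.04 in R141C at day 6 (SD, n = 2). The difference of -0.30 did not pass (adjusted p = 0.927). The 66 other tested genes within 1 Mb of it had a median difference of 0.09 at day 6 and -0.01 at day 0, with a smallest adjusted p of 0.380 at day 6.

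Of the 35 gene lists, camera called 18 as shifted at day 6, 3 higher and 15 lower in R141C. With an estimated correlation none was called (smallest adjusted p = 0.155), and fry called 2, neuroectoderm and interferon. Whichever array was left out, 6 of the 18 calls were kept, those of the sarcomere, cardiac transcription factor, retinoic acid, neuroectoderm, Hox and interferon lists. Among the called lists the median, the mean and the test had the same sign. No gene of the cardiac sarcomere and calcium handling list passed over all genes, but 34 of 36 were lower in R141C, with a median of -2.42 (adjusted p = 2.96e-17, and adjusted p = 0.413 with an estimated correlation). Adjusted over the list alone, 9 genes were lower and 1 was higher. Without R141C day 6 replicate 1 the median was -0.93. The genes with its highest signals were Tpm1 (-0.63, adjusted p = 0.767) and Actc1 (-3.87, adjusted p = 0.537). Chosen after their values were seen, Nppa (-4.45, adjusted p = 0.281) and Ttn (-3.93, adjusted p = 0.499, above background on 1 of the 2 R141C arrays) were lower. The cardiac transcription factor list had a median of -0.33 over 27 genes, none passing and 1 lower when adjusted over the list alone (adjusted p = 1.39e-05, and adjusted p = 0.413 with an estimated correlation). Its median was -0.71 without R141C day 6 replicate 2. Zfpm1 (-0.09) and Tbx3 (1.36) had its highest signals. Chosen after their values were seen, Tbx1 (-4.37, adjusted p = 0.0711) and Tbx5 (-3.20, adjusted p = 0.333) were lower, while Gata4 (-0.33) and Tbx20 (0.08) differed little. The list of reported Nkx2-5 targets had a median of -0.65 over 21 genes, with 1 lower when adjusted over the list alone (adjusted p = 0.000985, and adjusted p = 0.450 with an estimated correlation). Without R141C day 6 replicate 1 its median was -0.23 (adjusted p = 0.116), and without replicate 2 it was -1.18. Actc1 and Id2 (-0.65) had its highest signals. The epicardium list had a median of -0.82 over 10 genes, 2 lower when adjusted over the list alone (adjusted p = 5.2e-05, and adjusted p = 0.413 with an estimated correlation). It was -0.48 without R141C day 6 replicate 1 (adjusted p = 0.188) and -1.69 without replicate 2. Krt19 (-0.48) and Wt1 (-0.94) had its highest signals. The smooth muscle list had a median of -0.88 over 12 genes (adjusted p = 0.00207, and adjusted p = 0.516 with an estimated correlation), and -0.27 without R141C day 6 replicate 1 (adjusted p = 0.141). The fibroblast and matrix list had -0.65 over 23 genes (adjusted p = 0.00405, and adjusted p = 0.6255 with an estimated correlation), and -0.02 without that array (adjusted p = 0.697). Its call was also lost without wild-type day 6 replicate 2 (-0.49, adjusted p = 0.0617).

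**Figure D1:**
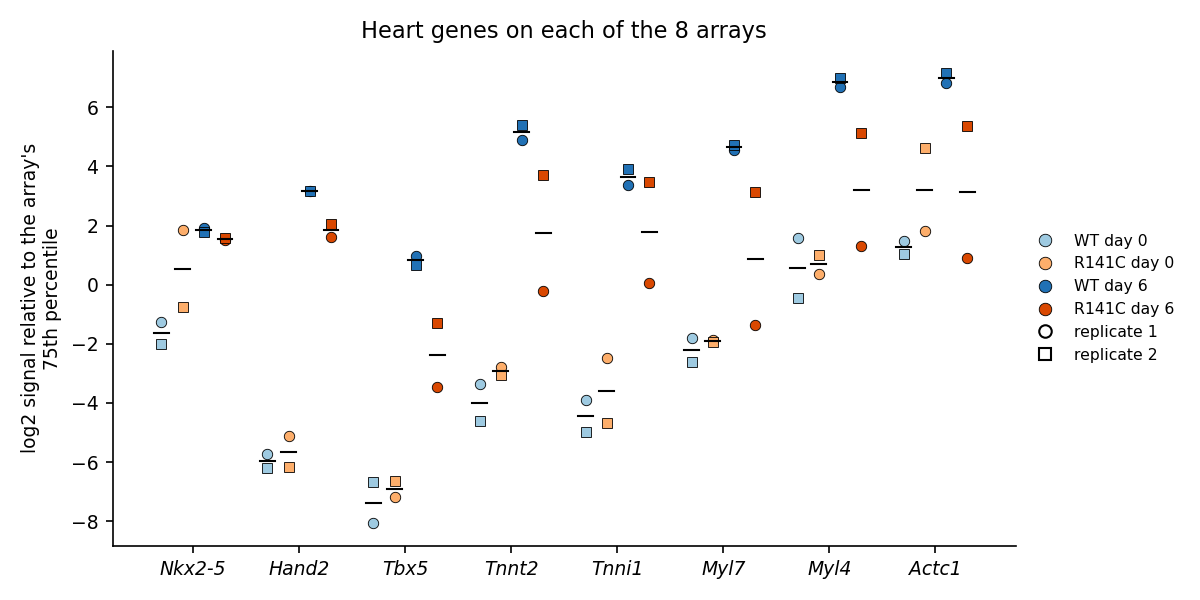
Log2 signal relative to the 75th percentile of the array for 8 heart genes on each of the 8 arrays, by group (colour) and replicate (shape), with group means as lines. At day 6, Nkx2-5 lay at 1.86 in wild type and 1.56 in R141C on average, while Tnnt2 lay at 5.16 and 1.74 with a standard deviation of 2.78 between the R141C cultures.

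The neuroectoderm list had a median of -0.79 over 21 genes, 4 of them lower when adjusted over the list alone (adjusted p = 9.5e-06, and adjusted p = 0.155 with an estimated correlation). Stmn2 (-1.25) and Nes (-1.30) had its highest signals, and Elavl3 (-2.38) and Tubb3 (-1.80), chosen after their values were seen, were among the lower genes. The retinoic acid list had a median of -0.57 over 17 genes, 2 lower when adjusted over the list alone (adjusted p = 0.000985, and adjusted p = 0.233 with an estimated correlation), and -0.16 without R141C day 6 replicate 1. Rxrb (0.18) and Rarg (0.63) had its highest signals. The Hox list had a median of 1.51, with 31 of 37 genes higher in R141C, and 3 higher and 2 lower when adjusted over the list alone (adjusted p = 1.53e-06, and adjusted p = 0.450 with an estimated correlation). Hoxb4 (-0.66), among its genes with the highest signals, was lower. Chosen after their values were seen, Hoxc11 (3.90), Hoxa10 (3.81) and Hoxa13 (2.31) were higher, all 3 above background on 1 of the 2 wild-type arrays, and Hoxa2 (-2.66) was lower. The interferon list had a median of 1.56, or 1.19 with dim genes at their bound, with 11 of 12 genes higher and 7 passing when adjusted over the list alone (adjusted p = 1.3e-06, and adjusted p = 0.155 with an estimated correlation). Ifitm3 (0.84) and Oas1a (1.76) had its highest signals, and Ifit1 (2.80, above background on 1 of the 2 wild-type arrays) and Oasl2 (2.71), chosen after their values were seen, were among the higher genes.

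**Figure D2:**
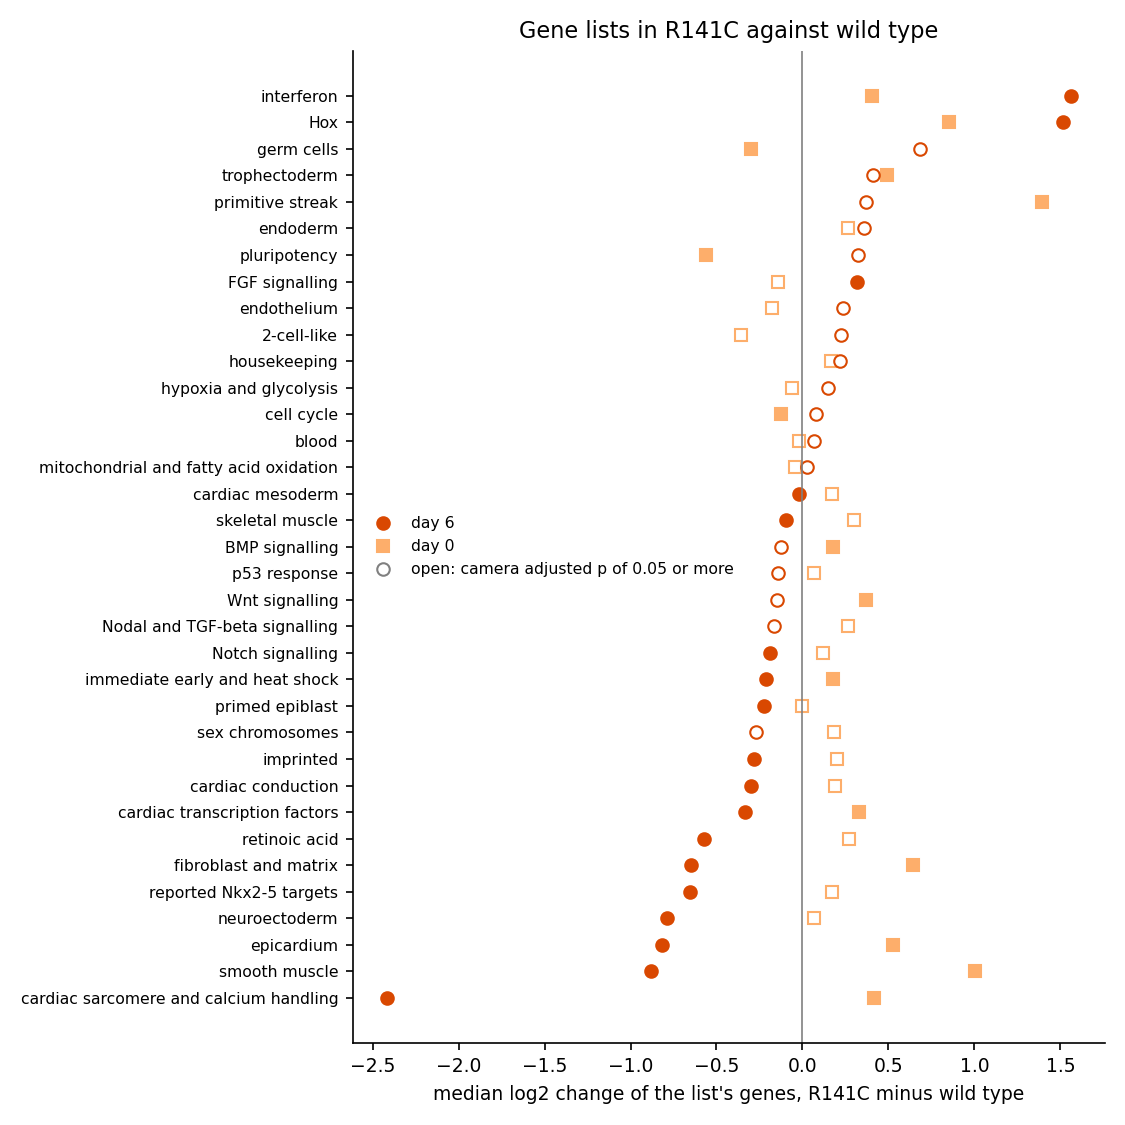
Median log2 difference between R141C and wild type of the genes of each of the 35 lists, at day 6 (circles) and day 0 (squares), filled where camera's adjusted p was under 0.05. The sarcomere list lay at -2.42 at day 6 and 0.41 at day 0, and the interferon list at 1.56 and 0.40.

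At day 0, R141C was compared with wild type to see how the cells differed before differentiation. No single gene passed. The genes of the undifferentiated state were on balance lower in R141C, and those of the primitive streak and the Hox clusters higher. None of the 3 lists was called with an estimated correlation (adjusted p = 0.600) or with fry (adjusted p = 0.748). Transcripts of Nkx2-5 differed more between the R141C cultures than between genotypes.

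In limma, 0 of 25892 genes changed at day 0 (smallest adjusted p = 0.0593), and 1166 had an unadjusted p under 0.05, 594 higher and 572 lower in R141C. The groups did not overlap for 28.8% of genes, where chance gives 33.3%. With normexp background correction, and with the filter on all 8 arrays, 1 gene passed. Among the 5 higher genes with the smallest p, none passing, were Pisd-ps2 (1.49), Zhx2 (at least 1.49-fold), Fam163a (2.55) and Hoxb1 (at least 7.43-fold), with adjusted p of 0.240 to 0.539. The lower ones were Kif5b (-2.76), Cldn24 (at least 5.13-fold), Necab1 (at least 1.41-fold), S100a7l2 (at least 1.42-fold) and Tex13b (at least 2.30-fold), with adjusted p of 0.0593 to 0.240. Kif5b was above background on all arrays, with 0.42 ± 0.20 in wild type and -2.34 ± 0.08 in R141C (SD, n = 2). Nkx2-5 was at -1.64 ± 0.54 in wild type and 0.54 ± 1.84 in R141C (SD, n = 2), a difference of 2.18 (adjusted p = 0.9995) that was 0.88 without R141C day 0 replicate 1 and 3.48 without replicate 2.

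Camera called 15 of the 35 lists at day 0, 12 higher and 3 lower in R141C, none of them with an estimated correlation (smallest adjusted p = 0.600) or with fry (smallest adjusted p = 0.748). Without wild-type day 0 replicate 2 it called 8 and without R141C day 0 replicate 2 it called 5. Whichever array was left out, 3 calls were kept. The pluripotency list had a median of -0.56 with 22 of 26 genes lower (adjusted p = 4.95e-05, and adjusted p = 0.600 with an estimated correlation). It had no gene passing when adjusted over the list alone. Its median was -0.29 without R141C day 0 replicate 2 and -0.37 without wild-type day 0 replicate 2. Its genes with the highest signal, Dppa5a (-0.05) and L1td1 (-0.13), differed little. The primitive streak list had a median of 1.39 over 16 genes, 8 of them higher when adjusted over the list alone (adjusted p = 1.24e-07, and adjusted p = 0.600 with an estimated correlation). Without R141C day 0 replicate 2 its median was 0.75. Sp5 (2.05) and T (2.41) had its highest signals. The Hox list had a median of 0.85 with 32 of 37 genes higher and 5 passing when adjusted over the list alone (adjusted p = 9.5e-09, and adjusted p = 0.600 with an estimated correlation). Its median was 0.35 without R141C day 0 replicate 1, 1.45 without R141C day 0 replicate 2 and 0.56 without wild-type day 0 replicate 2. Hoxb4 (1.49) was among its genes with the highest signals.

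No gene was called between the genotypes at both days. At an unadjusted p under 0.05, 93 genes were higher in R141C at both days, where 30.6 would be shared by independent lists (Fisher's exact test, p = 5.46e-22), and 61 were lower, where 19.4 would be (p = 2.49e-15). Genes are not independent, so these p-values are too small. Both tests of a gene also used the same variance estimate, which can raise the overlap. Genes changed in opposite directions were not counted, so the excess does not by itself show a shared genotype effect. Chosen after their values were seen, Cdx2 was higher by 2.56 at day 0 and 2.89 at day 6, and Oasl2 by 1.58 and 2.71. Kif5b was lower at both days, with -2.76 and -1.89.

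In wild-type cells, day 6 was compared with day 0 to describe the differentiation itself. Most transcripts of the undifferentiated state fell, and most of those on the lists of heart muscle, blood, endothelium and endoderm rose. Embryonic globins, transthyretin and cardiac troponin T were among the largest rises. Khdc3, Inhbb and Pou4f2 were among the largest falls.

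In limma, 6205 of 25892 genes (24.0%) changed in wild type, 2860 higher and 3345 lower at day 6, 5157 of them by at least 2-fold. The balance turned with other settings, to 3111 higher and 2759 lower with a median shift and 5703 higher and 3270 lower with no filter on dim probes. The count was 4015 without wild-type day 0 replicate 2, 2473 without day 6 replicate 1 and 2151 without day 6 replicate 2. The groups did not overlap for 71.3% of genes, where chance gives 33.3%. The median change of all genes was -0.12, against 0.0044 with a median shift and -0.04 with quantile normalization. The 10 largest rises were those of the globins Hba-x (at least 4546-fold), Hbb-bh1 (1528-fold), Hbb-y (1019-fold), Hba-a1 (640-fold), Hbb-b2 (at least 468-fold) and Hba-a2 (465-fold), and of Ttr (at least 1267-fold), Tnnt2 (569-fold), Hand2 (567-fold) and S100g (416-fold), with adjusted p of 0.000248 to 0.00298. Tnnt2 went from -3.996 ± 0.88 to 5.16 ± 0.36 and Hand2 from -5.97 ± 0.34 to 3.18 ± 0.01 (SD, n = 2). Among the 10 largest falls were those of Khdc3 (129-fold), Inhbb (98.8-fold), Pou4f2 (at least 95.8-fold), Aoah (60.9-fold), Eprn (59.6-fold), Mymx (58.3-fold), Accsl (57.2-fold), Hsd17b14 (54.3-fold) and Rhox10 (at least 50.9-fold), with adjusted p of 0.000455 to 0.0108. S100g at day 0 and Aoah at day 6 were above background on 1 of the 2 arrays, so their folds are imprecise. Without wild-type day 6 replicate 1 the adjusted p was 0.0577 for Inhbb, 0.0656 for Mymx and 0.0517 for Pou4f2. Leaving out 1 array moved some of these folds by more than 1.5 times. Without day 6 replicate 2 and without replicate 1, the rise was at least 2919-fold and 7080-fold for Hba-x, and in log2 9.09 and 10.90 for Hbb-y and 8.71 and 9.93 for Hba-a1. Without day 0 replicate 2 and without replicate 1 it was 8.53 and 9.78 for Tnnt2. The fall of Aoah was -5.32 without day 6 replicate 2. Its -6.53 without replicate 1 is not a measured fold, since Aoah was above background on 1 of these 2 arrays. Without day 0 replicates 2 and 1 the fall was -5.97 and -8.07 for Khdc3, -4.75 and -8.50 for Inhbb, -4.10 and -7.63 for Mymx, -6.74 and -5.06 for Eprn, -5.05 and -6.47 for Hsd17b14, and at least 23.0-fold and 112-fold for Rhox10. Nkx2-5 rose by 3.50, 11.3-fold (adjusted p = 0.0192), a call lost without wild-type day 0 replicate 2, day 6 replicate 1 or day 6 replicate 2, with an adjusted p of up to 0.0903 (without day 6 replicate 1).

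Camera called 23 lists in wild type, 19 higher and 4 lower at day 6, none with an estimated correlation (smallest adjusted p = 0.168), and fry called 22. Of the calls, 20 were kept whichever array was left out. In the pluripotency list 21 of 26 genes fell and 5 did not pass, with 23 lower when adjusted over the list alone and a median of -3.16 (adjusted p = 0.168 with an estimated correlation). Gdf3 (-5.48), Tcl1 (-5.33), Nr0b1 (-5.21) and Zfp42 (-4.998) fell most. Among cardiac transcription factors 18 of 27 rose and 9 did not pass, with 20 higher and 1 lower when adjusted over the list alone and a median of 3.72 (adjusted p = 0.168 with an estimated correlation). Hand2 (9.15), Tbx5 (at least 135-fold), Gata6 (7.17) and Isl1 (6.74) rose most. In the sarcomere list 21 of 36 genes rose, 1 fell and 14 did not pass, with 27 higher and 1 lower when adjusted over the list alone and a median of 3.80 (adjusted p = 0.265 with an estimated correlation). Tnni1 (8.08), Myl7 (6.87) and Myl4 (6.29) followed Tnnt2. The cardiac mesoderm list had 10 of 15 genes higher and 13 when adjusted over the list alone, with Foxf1 (8.04) and Pdgfra (7.83) first (adjusted p = 0.168 with an estimated correlation). In the endoderm list 17 of 24 rose and 2 fell, led by Ttr, Cer1 (at least 297-fold) and Afp (8.24), with 19 higher and 2 lower when adjusted over the list alone (adjusted p = 0.181 with an estimated correlation). In the endothelium list 18 of 25 rose and 1 fell, with Fli1 (7.93) and Cdh5 (7.17), both above background on 1 of the 2 day 0 arrays, among them, and 20 higher and 1 lower when adjusted over the list alone (adjusted p = 0.168 with an estimated correlation). In the blood list 17 of 21 rose and 1 fell, the same numbers as when adjusted over the list alone (adjusted p = 0.258 with an estimated correlation).

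In R141C cells, the same comparison of day 6 with day 0 asked which of these changes were called there too. Most genes of the blood, endoderm and endothelium lists rose, as did 13 of 27 cardiac transcription factors. Most genes of the contractile apparatus did not pass, which does not show that they failed to rise. Against the wild-type day 0 mean, the median of their list was 0.69 on R141C day 6 replicate 1 and 2.61 on replicate 2. On wild-type day 6 replicates 1 and 2 it was 3.73 and 3.87. Nkx2-5 was already at its day 6 level in 1 of the R141C cultures at day 0, and no rise was called.

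In limma, 4048 genes (15.6%) changed in R141C, 1968 higher and 2080 lower at day 6, 3510 by at least 2-fold. The count was 1619 and 2424 without R141C day 0 replicates 1 and 2, and 2570 without day 6 replicate 1. It was 2552 without either wild-type day 6 array, and 2459 with only the arrays compared. The groups did not overlap for 56.0% of genes, where chance gives 33.3%. Of the genes called, 3287 were also called in wild type, 3284 of them in the same direction, where 970 would be shared by independent lists. The largest rises were those of Hba-x (at least 1572-fold), Ttr (at least 981-fold), Hbb-y (973-fold), Hbb-bh1 (860-fold) and Prdm6 (804-fold), with adjusted p of 0.000437 to 0.00151. Prdm6 was above background on 1 of the 2 R141C arrays at day 0, so its fold is imprecise. The largest falls were those of Zscan4e (117-fold), Zscan4f (87.8-fold), Khdc3 (83.5-fold), Crct1 (64.9-fold) and Zscan4a (60.5-fold), with adjusted p of 0.00174 to 0.0390. Zscan4e and Zscan4a had the same limit at day 6. The calls of Zscan4e, Zscan4f and Zscan4a were lost without any 1 of the R141C arrays or either wild-type day 6 array, with an adjusted p for Zscan4e of up to 0.137 (without R141C day 0 replicate 2). Without R141C day 0 replicate 1 the change was 8.13 for Prdm6. Its 11.18 without replicate 2 is not a measured fold, since Prdm6 was above background on 1 of these 2 arrays. Without R141C day 0 replicates 1 and 2 the change was -5.19 and -7.57 for Khdc3, -8.05 and -5.68 for Zscan4e, -7.61 and -5.31 for Zscan4f and -6.91 and -4.93 for Zscan4a. Without day 6 replicates 1 and 2 the rise was at least 970-fold and 2547-fold for Hba-x and at least 1629-fold and 591-fold for Ttr. Nkx2-5 did not pass (1.02, adjusted p = 0.413), and its change was -0.28 without R141C day 0 replicate 2 and 2.32 without replicate 1.

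Camera called 20 lists in R141C, 16 higher and 4 lower at day 6, none with an estimated correlation (smallest adjusted p = 0.227), and fry called 19. Of the calls, 14 were kept whichever array was left out. In the pluripotency list 20 of 26 genes fell and Tbx3 rose (2.54), with 21 lower and 1 higher when adjusted over the list alone and a median of -2.51 (adjusted p = 0.230 with an estimated correlation). Nr0b1 (-5.66) and Gdf3 (-4.58) fell most. Among cardiac transcription factors 13 of 27 rose, 1 fell and 13 did not pass, with 16 higher and 1 lower when adjusted over the list alone and a median of 2.40 (adjusted p = 0.230 with an estimated correlation). Hand2 (7.49, above background on 1 of the 2 day 0 arrays), Gata6 (5.80) and Isl1 (5.60) rose most. In the sarcomere list 7 of 36 genes rose and 29 did not pass, with 8 higher when adjusted over the list alone. Its median was 1.09 (adjusted p = 0.00747, and adjusted p = 0.641 with an estimated correlation). It was 1.94 without R141C day 6 replicate 1 and 0.54 without replicate 2 (adjusted p = 0.462), and the call was also lost without R141C day 0 replicate 1 (median 1.08, adjusted p = 0.0926). Tmod1 (at least 26.6-fold), Tnni1 (5.36), Tnnt2 (4.66) and Mybpc3 (3.57) rose. In the blood list 17 of 21 genes rose and 1 fell, in the endoderm list 17 of 24 rose and in the endothelium list 17 of 25 rose, with 17, 19 and 20 higher and 1, 1 and 0 lower when adjusted over each list alone. The adjusted p with an estimated correlation was 0.258 for blood and 0.230 for endoderm and endothelium.

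The difference of the genotype effect between day 6 and day 0 tested whether R141C and wild-type cells differed in another way at day 6 than at day 0. No single gene passed. Of the lists called by camera, those of heart muscle, smooth muscle and epicardium had the largest medians. None was called with an estimated correlation (smallest adjusted p = 0.246) or with fry (smallest adjusted p = 0.148). Part of the difference came from day 0, where camera called these lists and cardiac transcription factors higher in R141C. At day 0 and day 6 the medians were 0.4139 and -2.416 for sarcomere and 1.002 and -0.8793 for smooth muscle. They were 0.5275 and -0.8175 for epicardium and 0.3311 and -0.3343 for cardiac transcription factors. Each of these day 0 calls was lost without wild-type day 0 replicate 2 and without R141C day 0 replicate 2.

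In limma, 0 of 25892 genes passed (smallest adjusted p = 0.122), 1460 had an unadjusted p under 0.05, and quantile normalization gave 7 and the deposited values 1. The genes with the smallest p, none passing, were Ces2h, Cldn24, Srgn (3.45), Amn (3.06) and Gria1 upward, and Foxd1, Lrrc39, Sncaip (-2.78), Foxb1 and Smpd3 (-2.995) downward. No value is given for the 6 of them that were below background on every array of at least 1 group. The difference for Nkx2-5 was -2.48 (adjusted p = 0.883), with -3.78 without R141C day 0 replicate 2 and -1.18 without replicate 1. Camera called 23 lists, 4 upward and 19 downward, none of them with an estimated correlation (smallest adjusted p = 0.246) or with fry (smallest adjusted p = 0.148), and 12 were kept whichever array was left out. The sarcomere list differed by -2.64 (adjusted p = 5.79e-17, and adjusted p = 0.250 with an estimated correlation), with -1.38 without R141C day 6 replicate 1 and -4.12 without replicate 2. No gene of it passed over all genes, and 1 was lower when adjusted over the list alone. Tpm1 (-1.85) and Actc1 (-5.82) had its highest signals. The smooth muscle list differed by -1.997 (adjusted p = 1.1e-06, and adjusted p = 0.275 with an estimated correlation), with -1.33, -1.20 and -1.16 without R141C day 0 replicate 2, R141C day 6 replicate 1 and wild-type day 0 replicate 2. The epicardium list differed by -1.61 (adjusted p = 6.99e-07, and adjusted p = 0.246 with an estimated correlation), with -1.07 without wild-type day 0 replicate 2. The cardiac transcription factor list differed by -1.38 (adjusted p = 7.09e-08, and adjusted p = 0.246 with an estimated correlation) and by -0.89 without wild-type day 0 replicate 2, with 1 gene lower when adjusted over the list alone. The pluripotency list differed by 0.69 (adjusted p = 4.09e-05, and adjusted p = 0.3 with an estimated correlation), with no gene passing when adjusted over the list alone.

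Replicate arrays of 1 group differed along whole chromosomes. Chromosome medians were taken over the tested genes well above background on all 8 arrays, after the median over all these genes was subtracted. In R141C at day 0, the genes of chromosomes 1, 8 and 19 had medians of 0.21, 0.28 and 0.27 for replicate 1 minus replicate 2, and at day 6 of 0.13, 0.28 and 0.33. In wild type, chromosome 1 had -0.25 at day 0 and -0.10 at day 6, and chromosome 8 had 0.25 and 0.15. Chromosome 11 was not kept across the days, with -0.02 at day 0 and 0.14 at day 6 in R141C, and 0.17 and -0.01 in wild type. Each median of chromosomes 1, 8 and 19 given here had a permutation p of 1e-04, the smallest that the permutations can give, and an adjusted p of 0.00032. Across the 20 chromosomes, which are not independent samples, the medians of day 0 and day 6 correlated with r of 0.915 and rho of 0.857 in R141C (permutation p = 1e-04) and with r of 0.776 and rho of 0.381 in wild type (permutation p = 7e-04). Between genotypes, chromosome 19 had a median of 0.15 at day 0 and 0.16 at day 6, which came from R141C replicate 1. Its median was 0.23 and 0.26 on the arrays of that replicate, -0.06 and -0.09 on those of R141C replicate 2, and between -0.06 and -0.10 on the 4 wild-type arrays.

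**Figure D3:**
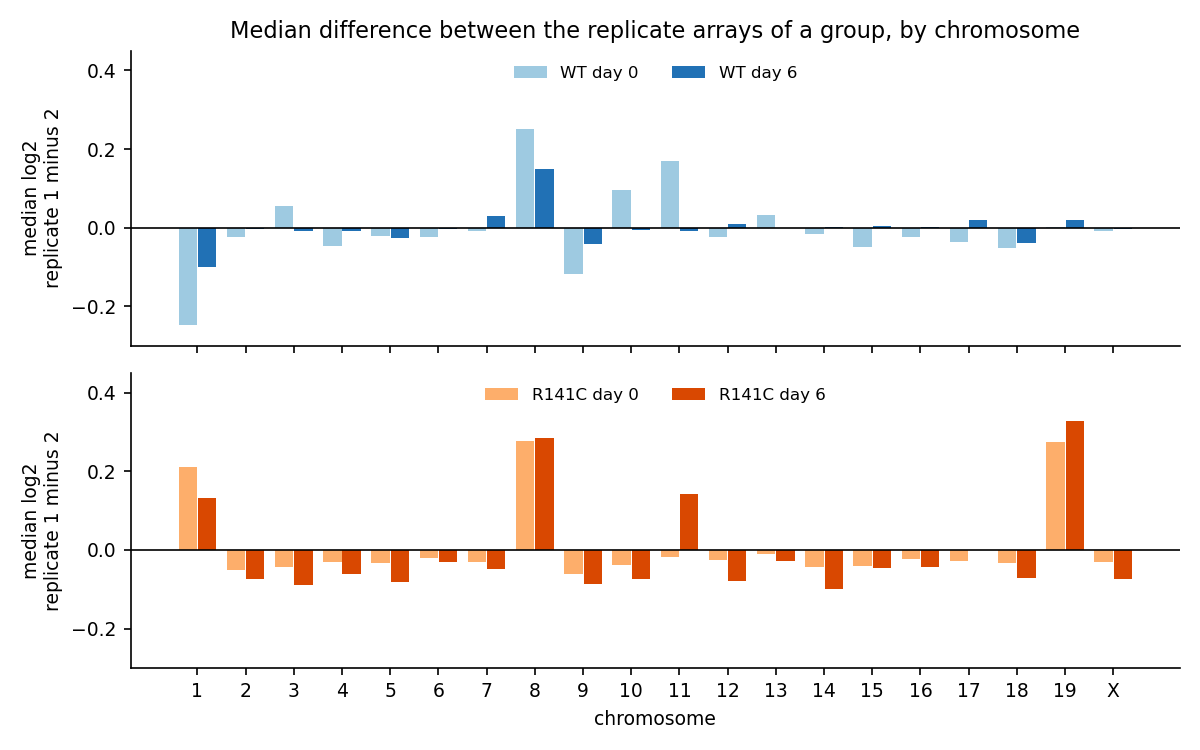
Median log2 difference between replicate 1 and replicate 2 of each group by chromosome, as bars, with wild type above and R141C below. Only tested genes well above background on all 8 arrays were used, and the median of each group over them was subtracted. Chromosomes 8 and 19 lay at 0.28 and 0.27 in R141C at day 0 and at 0.28 and 0.33 at day 6.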

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

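The tests of single libraries, scaling, chromosomes, a delay, a lower share of cardiac cells and day 6 RNA were chosen as tests of these patterns after the results were seen, while the interaction, the fits without 1 array, the scalings, the estimated correlation and fry were planned. What called attention to the lists below was the interaction term, which tested whether the effect of R141C differed between day 6 and day 0 and which camera passed for 23 lists. Genotype cannot be told apart from position on the slide or from the cell line, since each genotype had its own slide positions and no second line is in the labels.

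The medians of the difference, as the log2 effect at day 6 minus that at day 0, were negative for 19 lists. They were -2.638 for cardiac sarcomere and calcium handling, -1.997 for smooth muscle, -1.61 for epicardium, -1.377 for cardiac transcription factors, -1.166 for reported Nkx2-5 targets and -0.6455 for cardiac conduction. They were -0.9768 for neuroectoderm, -0.9462 for fibroblast and matrix, -0.8505 for retinoic acid, -0.7492 for primitive streak, -0.7264 for skeletal muscle, -0.6407 for immediate early and heat shock and -0.576 for imprinted genes. They were -0.4525 for Wnt, -0.3388 for Nodal and TGF-beta, -0.3174 for BMP and -0.2678 for Notch signalling, -0.2761 for primed epiblast and -0.01338 for cardiac mesoderm. They were positive for interferon (1.11), germ cells (0.7758), pluripotency (0.6872) and FGF signalling (0.4919). No list passed with an estimated correlation (smallest adjusted p = 0.246) or with fry (smallest adjusted p = 0.148).

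These medians depended on single arrays. With R141C day 0 replicate 2 left out, the call was lost for BMP signalling (-0.1678), Nodal and TGF-beta signalling (-0.1276), Notch signalling (0.006848), cardiac mesoderm (-0.08024), fibroblast and matrix (-0.2426) and primitive streak (-0.3485), and the median moved by over 1.5 times for cardiac conduction (-0.3862), germ cells (0.456), imprinted (-0.158), neuroectoderm (-0.6393), primed epiblast (-0.5527) and smooth muscle (-1.33). With R141C day 6 replicate 1 left out, the call was lost for BMP signalling (-0.134), Nodal and TGF-beta signalling (-0.1537), Notch signalling (-0.09701), imprinted (-0.03783), primed epiblast (-0.04395) and reported Nkx2-5 targets (-0.4035), and the median moved by over 1.5 times for cardiac mesoderm (-0.4203), sarcomere (-1.38), fibroblast and matrix (-0.5856), neuroectoderm (-0.4942) and smooth muscle (-1.196). With wild-type day 0 replicate 2 left out, the call was lost for BMP signalling (-0.1863), Nodal and TGF-beta signalling (-0.4287), cardiac mesoderm (-0.1609) and primed epiblast (-0.1526), and the median moved by over 1.5 times for FGF signalling (0.2745), cardiac transcription factors (-0.8909), epicardium (-1.07), fibroblast and matrix (-0.5434), germ cells (1.267), immediate early and heat shock (-0.3223), primitive streak (-0.3954), reported Nkx2-5 targets (-0.6033) and smooth muscle (-1.162). With wild-type day 6 replicate 1 left out, the call was lost for BMP signalling (-0.284), cardiac mesoderm (0.2279) and primed epiblast (-0.1474), and the median moved by over 1.5 times for primitive streak (-0.4391). With R141C day 6 replicate 2 left out, the call was lost for FGF signalling (0.5096) and cardiac mesoderm (-0.1744), and the median moved by over 1.5 times for Nodal and TGF-beta signalling (-0.6899), Notch signalling (-0.4203), sarcomere (-4.115), fibroblast and matrix (-1.728), germ cells (1.342) and primed epiblast (-0.6477). With wild-type day 0 replicate 1 left out, the call was lost for Nodal and TGF-beta signalling (-0.4027), and the median moved by over 1.5 times for FGF signalling (0.8442), cardiac mesoderm (-0.1032), fibroblast and matrix (-1.478), imprinted (-0.8755) and primed epiblast (-0.4568). With R141C day 0 replicate 1 left out, the call was lost for interferon (0.8017) and primed epiblast (-0.19), and the median moved by over 1.5 times for Nodal and TGF-beta signalling (-0.8866), Notch signalling (-0.5314), cardiac mesoderm (-0.08334) and fibroblast and matrix (-1.799). With wild-type day 6 replicate 2 left out, the call was lost for Nodal and TGF-beta signalling (-0.3515), and the median moved by over 1.5 times for cardiac mesoderm (-0.437), neuroectoderm (-0.638) and primed epiblast (-0.4477).

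The sarcomere list was lower in R141C at day 6 by camera, with no gene passing and with an adjusted p of 0.413 with an estimated correlation and 0.370 with fry. The tables argue against R141C day 6 replicate 1 as the only lower library, since the median without it was -0.9268, beyond the 0.2356 between the wild-type arrays. The R141C arrays lay further apart than that (-3.456 against -0.9268), so variation between cultures stays open as a cause. Scaling and background correction, with a highest median of -1.687 over 4 alternatives, and direct dosage of whole chromosomes, with no chromosome median between genotypes beyond 0.1613 in size, are argued against too. The 69 genes of the blood, endothelium and endoderm lists had a median of 0.2355 (interquartile range 1.129), which argues against a delay of these lineages. A delay that spared them was not tested, and camera called 15 lists lower and 3 higher, with smooth muscle, epicardium and neuroectoderm among the lower. A lower share of cardiac cells cannot be told apart from lower expression within them, because the cardiac transcription factors had a median of -0.3343 with genes going both ways, and indirect effects of chromosome copies stay open, because removing such small chromosome medians (-2.411) could not have ended the pattern and replicate 1, with higher chromosomes 1, 8 and 19, had the lower list median (-3.456 against -0.9268).

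Primitive streak and Hox genes were higher in R141C at day 0 by camera, with a median of 1.012 over 53 genes and an adjusted p for each list of 0.600 with an estimated correlation and 0.748 with fry. RNA of day 6 cells in the day 0 libraries would have to make up 7.498% as the median over 43 genes that need a share, from 0.237% (Hoxc8) to 100% (T among them). The gene set taken first to bound that share gave 0.05831% with a spread from -4.453% to 7.506%. The next, raised over 100-fold in both genotypes, gave 0.01573% but could give at most 1% by its selection, so neither decides. The last set was raised over 100-fold in wild type and, like the set before it, chosen after the earlier shares were seen. It leaves the R141C day 0 signal free, shares 8 of its 10 genes with the set before it and gave 0.01573% (range -0.1076% to 1.387%). This argues against such RNA at the median share needed, though genes such as Hoxc8 need less than the top of that range. These gene sets were chosen by their signal at day 6, so RNA of cells at an earlier stage of differentiation was not tested. A single library as the whole cause is argued against by medians of 0.6195 and 1.356 without R141C day 0 replicates 1 and 2. They were 1.265 and 0.8168 without wild-type day 0 replicates 1 and 2, against 0.5 between the wild-type arrays. The R141C arrays lay further apart than that, so variation between cultures stays open, and the Hox list alone fell to 0.3489 without R141C day 0 replicate 1. Direct dosage of whole chromosomes is argued against by a largest chromosome median of 0.1499 in size, while indirect effects of chromosome copies, which removing such medians (0.9896) could not test, an effect of the genotype and a difference between the lines may each remain.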

How the results depend on the processing

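Leaving out 2 R141C arrays together, removing chromosome medians, crossed replicate pairs and a block within each genotype were chosen after the results were seen. The other alternatives were planned.

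For R141C against wild type at day 6, the 17 genes became 15 with quantile normalization (13 shared), 5 with normexp and 1 with the deposited values. They became 0 without a filter, with the filter on all 8 arrays, with trend and robust settings, with only the arrays compared and without 2 R141C arrays (day 0 replicate 2 and day 6 replicate 1). Members of the cardiac lists passing at day 6 went from 0 to 1 with normexp. At day 0, normexp and the filter on all 8 arrays gave 1 gene each. The interaction gave 7 genes with quantile normalization and 1 with the deposited values. Day 6 against day 0 in wild type gave 2860 higher and 3345 lower genes, 3111 and 2759 with a median shift and 5703 and 3270 without a filter. Day 6 against day 0 in R141C gave 2459 genes with only the arrays compared and 1967 without the 2 arrays. The cause was not tested, except that fewer arrays leave fewer degrees of freedom.

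Leaving out 1 array, the lone sample of a group is assumed to vary like the other groups. Genes changed then ranged from 0 to 117 at day 6, 0 to 0 at day 0, 2151 to 6408 in wild type, 1619 to 4269 in R141C and 0 to 0 for the interaction, and passing members of the cardiac lists at day 6 from 0 to 13. Lists shifted ranged from 11 to 19 at day 6, 5 to 16 at day 0, 21 to 24 in wild type, 16 to 22 in R141C and 17 to 24 for the interaction. Without the 2 R141C arrays they numbered 11, 4 and 11 at day 6, at day 0 and for the interaction. With an estimated correlation they numbered 0 in each of the 5 comparisons, and fry gave 2, 0 and 0 at day 6, at day 0 and for the interaction.

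The direction of these results turned, for lists by camera. Nkx2-5 in R141C over time ranged from -0.281 (without R141C day 0 replicate 2) to 2.322, with -0.2545 without the 2 arrays. At day 0, fibroblast and matrix ranged from -0.09295 to 1.23 and cell cycle from -0.3548 to 0.1201, with -0.09295 and 0.1201 both without R141C day 0 replicate 2 and without the 2 arrays. At day 6, imprinted genes ranged from -0.4977 to 0.03278, and were 0.03278 without the 2 arrays. For the interaction without the 2 arrays, the direction camera gave turned for BMP (-0.07252), Notch (0.06879), Nodal and TGF-beta (0.08887), fibroblast and matrix (-0.04005) and imprinted genes (-0.1229). The cause was not tested. Medians of other called lists crossed 0 under some alternative while camera kept its direction: sarcomere (to -0.003809), trophectoderm (to -0.1636), immediate early and heat shock (to -0.03853) and germ cells (to 0.1406) at day 0, cardiac mesoderm (to 0.1116) and skeletal muscle (to 0.1021) at day 6, and cardiac mesoderm for the interaction (to 0.2279).

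Of 65 results for named genes, 58 kept direction and side of the threshold with quantile normalization, 63 with a median shift, 56 with normexp, 54 without a filter, 55 with trend and robust settings and 65 with a fold of at least 2 or the mean of all probes. Of 99 list results, 93 did with quantile normalization, 90 with a median shift, 98 with normexp and 41 with fry. With chromosome medians removed, 64 and 98 did. These counts pool the comparisons, and a gene result that did not pass counts as kept if it stayed so. For R141C against wild type at day 6, 82 of 219 values of 11 named genes stayed the same and 137 were weaker. Of these 11 results, 1 held in every setting. With fry, the lists kept were 2 between genotypes at day 6, 21 over time in wild type and 18 over time in R141C. They numbered 0 at day 0 and 0 for the interaction.

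With a replicate block, 0, 0, 6244, 3987 and 0 genes passed at day 6, at day 0, in wild type, in R141C and for the interaction. The difference of replicate 1 and 2 correlated across genes between day 0 and day 6 with r of 0.339 in R141C and -6.38e-05 in wild type, and across chromosomes with r of 0.915 and 0.776, so the numbers may pair the cultures. A block within each genotype gave 6437, 3812 and 0 genes over time and for the interaction. Crossed pairs at day 0 gave 0 genes. A block for the slide could not be fitted, with 1 slide. Signal over background limits what can be said of dim genes, with 74.5% of names tested.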

Other observations

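The tests of GC content, the gradient, the stretches of chromosomes, the interferon genes higher at both days and the correlation of imprinted genes were chosen after the results were seen, with chromosomes 1, 8 and 19 picked from the values, while the tests of the interferon list were planned.

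Whole chromosomes set replicate arrays apart in R141C. Probe GC content is argued against as the cause, since the lowest of the 6 medians of chromosomes 1, 8 and 19 was 0.151 with it removed. The lowest median on the upper or lower part of the arrays was 0.1312. That split was by row within the array, where trends had already been removed from the signal, so it cannot decide on a gradient across the slide. All 12 stretches of these chromosomes were higher in replicate 1 at both days. Gain or loss of whole chromosomes in part of the cells may explain this, and no DNA was measured.

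Interferon genes were higher in R141C at day 6 by camera (adjusted p = 0.155 with an estimated correlation), and 8 of 12 were higher at both days. A difference between the lines present before differentiation is a candidate explanation, which the day 0 values do not settle. At day 0 none of the 12 genes passed, with an adjusted p for the list of 0.0224 by camera and 0.600 with an estimated correlation. The call at day 0 was lost without wild-type day 0 replicate 1 (median 0.69 against 0.40, adjusted p = 0.0928), wild-type day 0 replicate 2 (adjusted p = 0.0931) or R141C day 0 replicate 2 (adjusted p = 0.5495).

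For imprinted genes in R141C, the difference of replicate 1 and 2 at day 0 correlated with that at day 6 across the 23 genes. The r was 0.7696, above the 95th percentile of 0.7279 of 10000 random gene sets (permutation p = 0.0259). In wild type r was 0.4966, and no random gene sets were drawn there. Over all tested genes r was 0.339 in R141C and -6.38e-05 in wild type, so the values do not set R141C apart. Of the 23 genes, 11 were lower in replicate 1 at both days, and the share over all genes was not counted. A state of the culture kept from day 0 to day 6 may explain this.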
